A study of Danio rerio with 2 samples.

How the data were processed

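Whole zebrafish larvae were swim-trained or left untrained, and their RNA was compared on 2-colour Agilent oligonucleotide arrays. Per the labels' protocols, training ran from 5 to 10 days after fertilisation in sessions of 3 hours, and larvae were sampled at 10 days. Per the labels, 400 ng of RNA from each of 10 fish was pooled per condition, and 100 ng of each pool was labelled. The same 2 pools were hybridised on 2 arrays with the dyes exchanged. On array 1 the trained pool carried Cy5 and the control pool Cy3, and on array 2 the dyes were the other way round. The 2 arrays are a technical dye swap and count as 1 replicate. With 1 pool per condition there are no biological replicates, so no p-value, standard error or standard deviation across fish was computed.

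Per the file headers, each scanner file held the median foreground and background intensity of every spot in both channels, flags for outliers, saturation and signal well above background, and Agilent's processed signals. Per the submitters' processing notes, Agilent Feature Extraction 10.5.1.1 was used. The deposited log10 ratio of each scanner file is Cy5 over Cy3 after the background and dye steps of that software. It was listed as exactly 0 for 4289 spots of array 1 and 5574 of array 2. The deposited series value table held log10 ratios with a median of 0 in each column. Set against the scanner files, it equals their log10 ratio with the sign of array 2 turned, so both columns are trained over control. The other unit in the scanner files was the authors' deposited flags, which are not measurements.

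The ratios were rebuilt from the median intensities with limma 3.58.1 in R 4.3.3. Mean spot signals had been planned, and median signals were used in their place. Background was corrected by normexp with an offset of 50, and each array was normalised by loess with control and outlier spots at weight 0. Array 2 was sign-flipped, the spots of a probe were averaged, and the 2 arrays were averaged. Of 43603 probes, 43600 had a spot free of outlier flags, and 13 spots were left out. A probe was called measured when both channels of both arrays were well above background, which held for 30887 probes or 70.8%. No spot was saturated.

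Gene symbols came from matching the unversioned accession of a probe to a RefSeq gene table of assembly GRCz12tu. This named 25171 probes and left 18429 unnamed. The array was designed on an older build, so no coordinates are given. A gene was represented by its brightest measured probe, which gave 11121 genes. Later steps used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and correlations used scipy 1.17.1.

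No test across fish was possible, and a size rule was used in its place. A probe passed with a ratio of at least 1.5-fold in the same direction on both arrays. Probes passing in the same dye direction on both arrays were counted as a technical floor. The dye component of a probe was the mean of its ratios of both arrays before the sign of array 2 was turned. The correlation of the arrays had been planned as a check of the dye orientation, with a value above 0 awaited for a swap. Lists of genes for 17 tissues and 18 functions were fixed before the data were examined. The median of each was set against 10000 random lists of the same size matched on brightness in 20 bins. A list was called apart when its median lay outside the central 95% of the random lists and on the same side of the random median on each array. The percentiles describe these 2 pools, not the conditions.

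Named genes followed a rule fixed before the data were examined. It took the 12 highest and 12 lowest genes passing the size rule, ranked by the smaller of the 2 arrays' ratios. For lists outside the random range it took up to 4 members in the list's direction and the strongest opposite member that passed. For other lists it took at most 2 passing members. It added 16 genes fixed by name, and up to 5 genes per direction detected in 1 pool only.

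The size rule and the list step were tested on simulated arrays with known ratios over 30887 probes. For trained over control, 96% of probes simulated at 2-fold higher were recovered, 90% at 0.5-fold, 100% at 3-fold and 12% at 1.5-fold. Of 200 simulated lists without a change, 5.5% fell outside the random range. They were drawn at random from the same genes as the random lists, so this share was fixed by construction. It is no error rate for lists whose genes vary together. The simulated noise was the spread between spots and the dye effect, without any spread between fish.

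Alternatives were no background correction, normexp with an offset of 0, median centring, the deposited ratios, the series value table, a looser detection filter, saturated spots left out, each array alone, thresholds of 2-fold and 1.2-fold, and the mean over a gene's probes. Chosen after seeing the data were 3 further lists, lists without passing genes, a list direction read from the sign of the median on each array, and a 1.5-fold rule on the mean of both arrays.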

Results

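RNA of whole zebrafish larvae aged 10 days was compared between a pool of 10 swim-trained fish and a pool of 10 untrained control fish, to ask which transcripts differ after training. There were no biological replicates, and the 2 arrays measured the same 2 pools with the dyes exchanged. All values below describe these pools. The median spot signal was 137.5 in Cy3 and 178.5 in Cy5 on array 1, over median backgrounds of 24.5 and 82.5. On array 2 it was 136 in Cy3 and 155.5 in Cy5, over backgrounds of 24 and 82. Between 71.3% and 84.2% of spots were well above background in a channel. The number of arrays limits the precision.

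In the trained pool 147 of 30887 measured probes were at least 1.5-fold higher on both arrays, and 13 were at least 1.5-fold lower. These counts depended on the processing, with 273 and 69 under the deposited ratios and 230 and 35 with an offset of 0. At gene level 71 genes were higher and 6 were lower. The highest was pde6ha, a cone photoreceptor phosphodiesterase subunit, at 2.94-fold higher, with a mean log2 ratio of 1.55 over the 2 arrays. The ratio was 1.08 on array 1 and 1.23 on array 2 for the inducible chaperone hsp70.3, and the mean was 1.16 for tdo2b, which breaks down tryptophan. The arrays gave 1.11 and 1.00 for socs1a, a cytokine signalling inhibitor, and 1.02 and 0.98 for cyp24a1, which degrades vitamin D. The lysosomal enzymes naga, ctsl.1 and ctsz had mean log2 ratios of 1.01, 0.95 and 0.97, and ifi30a, a lysosomal thiol reductase, had 1.01. The mitochondrial uncoupling protein ucp1 stood at 1.23, the immediate early gene egr4 at 1.21 and the plasma protein gene ahsg1 at 0.99.

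The 6 lower genes included 2 that encode nuclear receptors of the circadian clock, nr1d2a and nr1d1, with mean log2 ratios of -0.92 and -0.68. Over the 8 alternatives run on both arrays nr1d2a ranged from -1.08 to -0.51 and nr1d1 from -1.61 to -0.60. The glucocorticoid-induced genes fkbp5 and klf9 stood at -1.09 and -0.84, which is 2.13-fold and 1.79-fold lower in the trained pool. Over these alternatives fkbp5 ranged from -1.35 to -0.77 and klf9 from -1.25 to -0.73. A second probe of fkbp5 stood at only -0.46, with -0.39 and -0.52 on the arrays, and did not pass the size rule. A second probe of klf9 stood at -0.61. The Kruppel-like factor klf3 stood at -0.81 and the lens crystallin crygs1 at -0.67, with a range of -1.24 to -0.63. For nr1d2a 1 of 2 other measured probes was opposite in sign, at 0.10, and the other stood at -0.71.

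**Figure D1:**
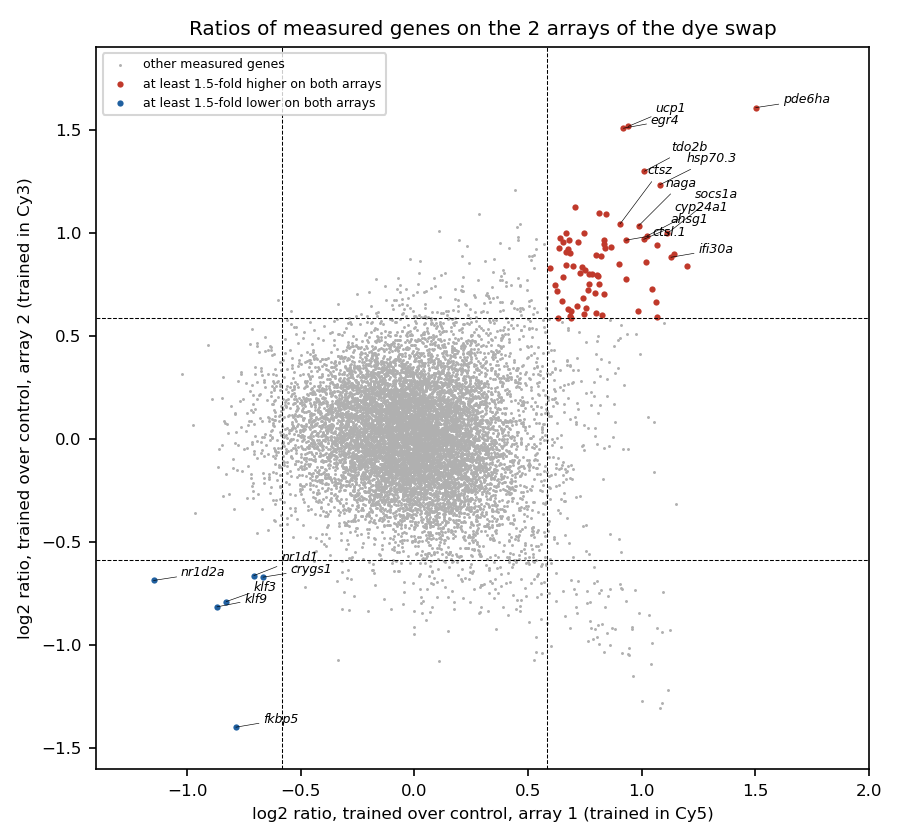
Each point is a measured gene, with its log2 ratio of trained over control on array 1 (horizontal) and array 2 (vertical); dashed lines mark 1.5-fold. The 71 higher genes lie at the upper right and the 6 lower genes at the lower left.

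Of 35 gene lists, 10 were apart from random lists on the higher side and 5 on the lower side, each on the same side of the random median on both arrays. Of these, 6 lay outside the random range on each array alone, which were liver, intestine, photoreceptor, skin and fin fold, immediate early and cell cycle genes. About 1.75 lists outside the range on the mean were awaited by chance, and 17 were. The figure of 1.75 takes the genes of a list to vary independently, which was not tested. On the dye component 4 of the 35 lists lay outside the random range. Of 18 measured liver genes 10 were higher on both arrays, 2 lower and 6 opposite, with a median log2 ratio of 0.28 at percentile 100 of the random lists. The array medians were 0.23 and 0.42, and without passing genes array 1 was inside the random range at percentile 94.8. The plasma protein genes apoa2 and ambp and the urate oxidase gene uox had mean ratios of 0.76, 0.69 and 0.74. Among 17 measured intestine genes 7 were higher on both arrays and 3 lower, with a median of 0.11 at percentile 98.7, and of 0.19 and 0.25 on the single arrays. The intestine list members anpepb.1, rbp2b, ada and slc5a1 had ratios of 0.87, 0.87, 0.74 and 0.68. Without its 3 passing genes the intestine median was 0.07 at percentile 90.8, inside the random range.

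Of 29 measured photoreceptor genes 18 were higher on both arrays and 2 lower, with a median of 0.19 at percentile 100, and of 0.17 and 0.37 on the single arrays. Besides pde6ha, the cone genes pde6c, grk7a and grk1b had ratios of 0.85, 0.78 and 0.77. The median of 30 skin and fin fold genes was 0.15 at percentile 100, and 0.18 and 0.13 on the arrays, with cyt1 at 0.57, ppl at 0.42, cyt1l at 0.36 and anxa1b at 0.31. For cyt1l 2 of 6 other probes were opposite in sign. Of 36 immediate early genes 20 were higher on both arrays and 3 lower, with a median of 0.14 at percentile 100. The array medians were 0.13 and 0.25, and without passing genes the median was 0.09, with array 1 inside the random range at percentile 97.4. Besides egr4, socs3a stood at 0.95, npas4a at 0.71 and fosab at 0.55.

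The exocrine pancreas list had a median of 0.10 at percentile 99.4, and 13 of its 20 genes were opposite on the arrays. Its median was 0.19 on array 1 and -0.01 on array 2, at percentile 53.1, so the shift was absent on array 2. Its members amy2a, sycn.2, cpa4 and amy2al1 had ratios of 0.77, 0.51, 0.42 and 0.14, and another probe of amy2al1 was at -0.12. Without its passing gene the list was no longer apart, with a median of 0.10. The endocrine pancreas list had a median of 0.14 at percentile 98.9, with gcga at 0.38, sst1.1 at 0.20 and pdx1 at 0.18. Its median was 0.20 on array 1 and 0.06 on array 2, at percentile 66, inside the random range. Of its 10 genes 7 were opposite on the arrays. The median of its dye component was 0.13 and lay outside the random range too. The heart list had a median of 0.11 at percentile 98, with cmlc1 at 0.61, myh7l at 0.49, myl7 at 0.42 and tnnt2a at 0.34. The array medians were 0.10 and 0.12, both inside the random range. The myeloid list had a median of 0.10 at percentile 98.0, with lyz at 0.42, irf8 at 0.33, grna at 0.28 and cebp1 at 0.13. It too lay inside the random range on either array, with medians of 0.06 at percentile 78.5 and 0.15 at 95.1. Fatty acid synthesis and storage genes had a median of 0.09 at percentile 97.5, with dgat2 at 0.47, g0s2 at 0.45, cebpa at 0.42 and pparg at 0.14. For cebpa, 1 of 2 other probes was at -0.10. The list was inside the random range on either array, with a median of 0.04 on each, and 7 genes were higher on both arrays, 4 lower and 8 opposite. The lower genes included plin2 at -0.43 and aclya at -0.28, which were chosen after their values were seen.

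With the dyes swapped as labelled, cell cycle genes formed the lowest list. Of 40 measured genes 26 were lower on both arrays, 3 higher and 11 opposite. The median was -0.26, at -0.20 on array 1 and -0.24 on array 2, below every one of the 10000 random lists. The replication genes mcm5 and mcm4 had ratios of -0.56 and -0.47, and esco2 and ttk had -0.37 and -0.33. No member passed the size rule, and 1 other probe of mcm4 was at 0.10. Of 28 lens genes 13 were lower on both arrays and 1 higher, with a median of -0.12 at percentile 0.13. On either array alone the lens list lay inside the random range, at percentiles 3.22 and 3.95. Its median ranged from -0.19 to -0.04 over the alternatives run on both arrays. Its members included crybb1l3 at -0.45, lim2.1 at -0.31 and crybb1 at -0.26. For crybb1, 1 of 3 other probes was at 0.02. Of 37 proteasome genes 14 were lower on both arrays and 4 higher, with a median of -0.12 at percentile 0.2. On array 2 alone the median was -0.06 at percentile 10.2, inside the random range, and alternatives gave -0.13 to -0.05. Its members included psmd13 at -0.35, psmd10 at -0.33, psmc5 at -0.28 and psmd7 at -0.23. For psmd13, 1 of 2 other probes was at 0.14.

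Of 29 heat shock and chaperone genes 10 were lower on both arrays and 7 higher, with a median of -0.11 at percentile 0.58. The array medians were -0.08 and -0.04, both inside the random range. In 4 of 8 alternatives run on both arrays the list was no longer apart, with a range of -0.11 to -0.02. Lower members included hspb9 at -0.48, hspa5 at -0.41, serpinh1b at -0.36 and hspb8 at -0.34. The 2 members that passed the size rule, hsp70.3 and hsp70l, were higher, at 1.16 and 0.90. Of 24 cholesterol synthesis genes 11 were lower on both arrays, 5 higher and 8 opposite, with a median of -0.10 at percentile 2.36. The array medians were -0.13 and -0.07, both inside the random range. It was apart in only 3 of those 8 alternatives, with a range of -0.10 to -0.04. Lower members included idi1 at -0.47, ldlra at -0.40, insig1 at -0.39 and acat2 at -0.37. Among the higher members msmo1 stood at 0.50 and nsdhl at 0.26, which were chosen after their values were seen.

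**Figure D2:**
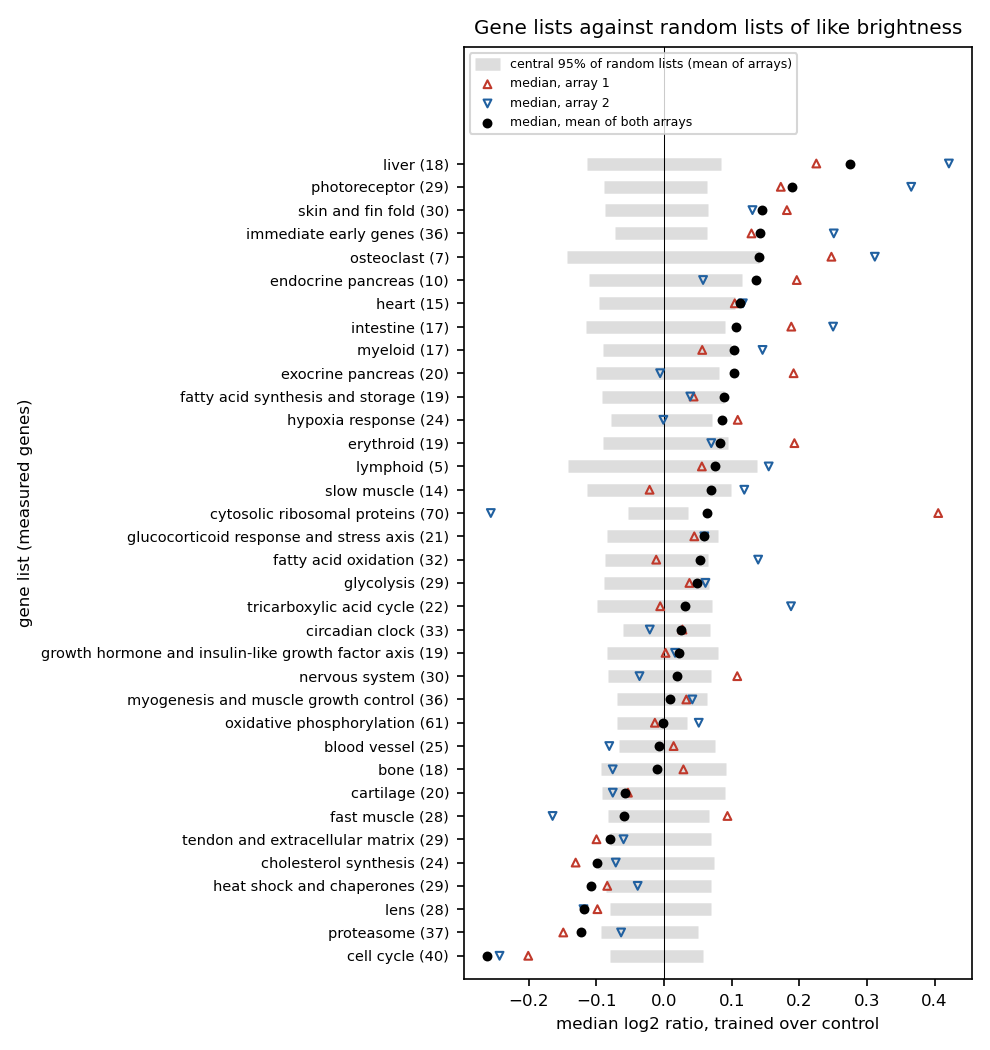
Each row is a gene list with its number of measured genes; points are the median log2 ratio of trained over control on each array and on their mean, and grey bars hold the central 95% of 10000 random lists. With the dyes swapped as labelled, the cell cycle median of -0.26 lies lowest and the liver median of 0.28 highest.

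The hypoxia list had a median of 0.09 at percentile 99.1, with array 2 on the other side of the random median. Its members hmox1a, igfbp1b, mb and ngb stood at 0.41, 0.29, 0.25 and 0.13. Cytosolic ribosomal protein genes followed the dye, with medians of 0.41 on array 1 and -0.26 on array 2, and 59 of 70 genes were opposite on the arrays. Their mean was 0.06 at percentile 99.8, and rpl4, rps28, rpl10a and rps10 stood at 0.32, 0.29, 0.23 and 0.19. Other probes of rpl4 and rps28 were at -0.10 and -0.01.

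Lists of muscle lay inside the random range, with medians of -0.06 for fast muscle at percentile 10.4 and 0.07 for slow muscle at percentile 92.6. The arrays disagreed on both. Fast muscle had array medians of 0.09 and -0.16, with 25 of 28 genes opposite, and slow muscle -0.02 and 0.12, with 10 of 14 opposite. The medians near 0 thus do not show that muscle genes were unchanged. Also inside the random range were bone at -0.01 and percentile 43.0, cartilage at -0.06 and 12.4, and osteoclast at 0.14 and 97.5. The osteoclast list, of 7 genes, was apart on the higher side in 6 of 8 alternatives run on both arrays, with medians of 0.14 to 0.26, and on each array alone. Erythroid genes had a median of 0.08 at percentile 95.3, lymphoid genes 0.08 at 88.1 and nervous system genes 0.02 at 75.3. Glycolysis genes had a median of 0.05 at percentile 93.5, though pklr and ldhbb passed the size rule at 0.89 and 0.66. Oxidative phosphorylation stood at 0.00 and percentile 72.1, the tricarboxylic acid cycle at 0.03 and 86.2, and fatty acid oxidation at 0.05 and 95.7. Blood vessel genes had -0.01 at percentile 39.5, and tendon and extracellular matrix genes had -0.08 at 2.68. Myogenesis and muscle growth control stood at 0.01 and percentile 63.8, and the growth hormone and insulin-like growth factor axis at 0.02 and 72.9. The circadian clock list had a median of 0.03 at percentile 76.8, with bhlhe40 higher at 0.79 and nr1d2a and nr1d1 lower. The glucocorticoid list had a median of 0.06 at percentile 93.2, with socs1a higher and klf9 and fkbp5 lower.

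**Figure D3:**
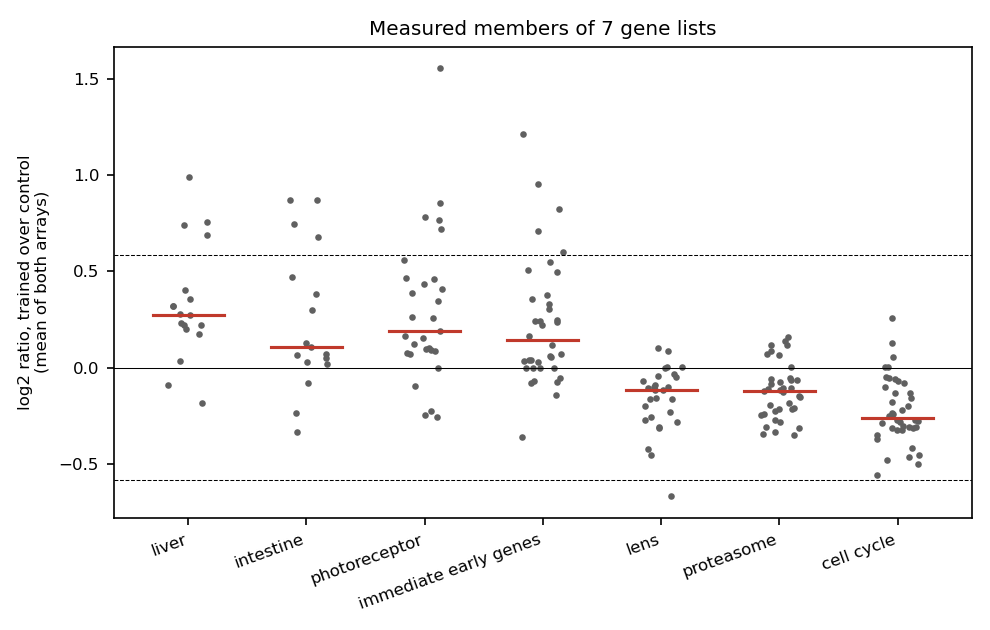
Each point is a measured gene of a list, with its log2 ratio of trained over control averaged over both arrays; red bars are list medians and dashed lines mark 1.5-fold. Photoreceptor genes reach 1.55, and no cell cycle gene lies beyond the lower line.

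Several genes of bone, muscle and growth had been named in advance. The cartilage regulator sox9a stood at 0.21, with another probe at -0.06, and vegfaa at 0.16. Myostatin (mstnb) stood at -0.11, with 3 of 5 other probes opposite in sign. The bone genes sp7, runx2b and col10a1a, the myosin genes smyhc1 and myhz2, nppa and igf1 were opposite on the arrays, so no direction is given for them. Array 1 and array 2 gave -0.08 and 0.29 for smyhc1, 0.12 and -0.46 for myhz2, and 0.25 and -0.02 for nppa. No probe was paired here with ppargc1a or hif1ab.

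In all, 35 probes were well above background on both arrays in the trained pool and on neither in the control pool, and 14 the other way. The former included cfhl3, cbln9, taar12j and ikzf1, and the latter sema4c and zp2.3. Only a lower bound of the fold can be had for them, because the other pool was not well above background. For these 6 genes it ran from 1.05 for zp2.3 to 1.34 for cfhl3. Of the 35 probes 1 had a bound of at least 1.5-fold, and of the 14 it was 0. Detection in 1 pool only does not show absence from the other. The ratios of trim35-34 and pou5f3, detected in 1 pool only, were opposite on the arrays.

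The dye component varied as much over probes as the mean ratio, with an SD of 0.19 against 0.18. Both also hold noise of the arrays and spots, so neither SD is the size of a dye effect or of a pool difference alone. Under the same 1.5-fold rule 116 probes followed the dye, 113 towards Cy5 and 3 towards Cy3, against 160 that followed the condition. Across 30887 probes the trained over control ratios of the 2 arrays had a Pearson r of -0.04 and a Spearman rho of -0.09. A value above 0 had been set in advance as the check of the dye orientation, and it was not met. Under the deposited ratios the Pearson r was 0.11, which is above 0, so the outcome of the check depended on the processing. The directions above therefore rest on the sample titles, the channel labels and the sign turned in the series value table. The series' design text repeats 1 orientation, and without a swap the 113 and 3 probes could follow the condition or the dye. The dye component would then hold the ratio of the pools, up to its sign, mixed with a dye effect that nothing cancels. Its list medians ran from -0.14 for the tricarboxylic acid cycle to 0.35 for cytosolic ribosomal proteins, with cell cycle at -0.04 and liver at -0.08. The agreement between probes of a gene, given below, argues against this case.

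The spread between spots of a probe was 0.09 (SD, log2, mean of both arrays, 21 probes), and that between probes of a gene was 0.12. Agreement between probes of a gene was examined after the values had been seen. Across 6037 genes with 2 measured probes, the mean ratio correlated between probes with an r of 0.61, and the dye component with 0.11. Without a swap, the mean ratio would hold array differences only, and the difference of the pools would lie in the dye component. The higher agreement of the mean ratio argues against that. It does not show which pool carried which dye on an array. Genes are not independent replicates. Of 52 passing genes with a second measured probe, 52 had it in the same direction, with a median ratio of 0.62. In the statistics of Feature Extraction, spike-in ratios had a slope of 0.868 on array 1 and 0.867 on array 2 against their known values. The ratios of that software were thus compressed, and no slope was computed for the rebuilt ratios.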

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

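Leaving passing genes out of the lists, the sign of the list median on each array and the rule on the mean of both arrays were chosen after seeing the data. No paired analysis was possible because the arrays form 1 group of the same 2 pools. With 1 pool per condition the ranges show processing, not spread between fish. All 31 named genes passing the size rule kept their sign in the 8 alternatives run on both arrays, and the log2 ratio of 6 moved by over 1.5 times: nr1d1, nr1d2a, crygs1, ada, bhlhe40 and grk7a. The latter 3 stood at 0.47, 0.41 and 0.43 at the lowest. Of the 15 lists 9 stayed apart in the same direction. The 8 alternatives are not all distinct. The deposited ratios and the series value table gave the same values, and leaving out saturated spots repeated the main result. Counts out of 8 include these repeats. The cell cycle median ranged from -0.27 to -0.18, photoreceptor from 0.19 to 0.26 and liver from 0.27 to 0.36, and on array 2 alone the latter 2 were 0.37 and 0.42. Cholesterol synthesis and fatty acid synthesis each stayed apart in 3 of 8, heat shock in 4, and endocrine pancreas, heart and myeloid in 7. On a single array 6 of the 15 lists were apart on each, 3 on 1 and 6 on neither. Lens, among the 9, was apart on neither and proteasome and exocrine pancreas on array 1 only. Of the other lists 8 became apart in at least 1 alternative, osteoclast in 6 and fatty acid oxidation in 3, both higher. Without passing genes 13 of the 15 lists stayed apart, and intestine and exocrine pancreas did not. Lists without a passing gene, among them cell cycle, proteasome, heart and skin and fin fold, could not change in this step. For heat shock the genes left out lay against the direction of the list. The count of 13 is therefore little evidence of stability. With passing genes kept, 14 of the 15 had the same sign of the median on both arrays. Being apart had already required the same side of the random median, so this count was largely fixed in advance.

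Probes higher in the trained pool numbered 147, lower 13 and following the dye 116. With an offset of 0 these were 230, 35 and 199. With median centring 6 were lower, 210 followed the dye, and the correlation of the arrays was -0.17. The deposited ratios and the series value table, which hold the same values, each gave 273 higher, 69 lower, 197 following the dye and a correlation of 0.11, opposite in sign to -0.04. Higher probes then made up 79.8% of passing probes, against 91.9%. At 2-fold the counts were 17, 1 and 9, and at 1.2-fold 967, 363 and 1608. At 1.2-fold more probes followed the dye than the condition. Leaving out either array gave 496 to 614 higher and 440 to 503 lower. A single array loses both the cancelling of the dye and the rule that a probe pass on both arrays, and these were not separated. On the mean of both arrays, which keeps only the first, 252 were higher and 37 lower. No count following the dye can be had from 1 array. Leaving out saturated spots moved nothing, as there were none. Apart from the thresholds, the cause was not tested. Signal over background limits dim probes, and 70.8% of probes were measured.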

Other observations

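The 3 lists in this paragraph were written after the highest genes had been seen, so their direction is not independent evidence. Of 46 measured lysosomal genes 35 were higher on both arrays and 2 lower, with a median log2 ratio of 0.36, and 0.30 without the 8 that passed the size rule. Of 17 interferon and antigen presentation genes 13 were higher on both arrays and 0 lower, with a median of 0.40, and 0.37 without passing genes. Of 37 genes of amino acid catabolism 19 were higher on both arrays and 0 lower, with a median of 0.28, and 0.24 without passing genes. All 3 medians lay at percentile 100 of the random lists. In a split of the photoreceptor list chosen after the values were seen, 14 cone genes had a median of 0.37 and 10 rod genes 0.09, a difference that was not tested.

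Of the tests below, those on glucocorticoid signalling, on photoreceptor cells and on the dye effect were chosen only after the result was seen. Those on second probes were set when the agreement between probes over all genes was known. The medians of the whole lists under the main processing had been seen before any test was set.

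The pattern of lower cell cycle genes may reflect the pools themselves. With the dyes swapped as labelled, a dye effect would have moved the list to opposite sides on the arrays, but it was lower on both, and its median nearer 0 was -0.201 (SE over genes 0.047). Being apart had already required the same side. It had not required a median outside the random range on each array, and this list lay at percentile 0 on both. Noise of single probes would have left other probes of the genes without the shift, but 26 second probes had a median of -0.181 (SE 0.024), below the range of random second probes. For background correction or loess, a median inside the random range under the deposited ratios had been set as the prediction. It was -0.241, outside the range on the lower side. Those ratios have background and dye steps of their own, so they alone decide nothing. Without background correction the median was -0.26, and with median centring in place of loess -0.20, both at percentile 0. These values argue against each of the 3 technical sources as the whole cause, and a difference in growth stage or in tissue make-up between the pools, or between the individual fish in them, stays open as untested.

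For nr1d1, nr1d2a, fkbp5 and klf9, lower in the trained pool, no explanation tested was decided. With the dyes swapped as labelled, their median on the array nearer 0 was -0.75 (SE 0.196), with each gene lower on both arrays. A dye effect would put genes on opposite sides. The size rule had picked these genes for lying on the same side, so their position decides nothing. If the pools differ in clock time, clock genes of the opposite phase could be at least 0.3 higher, and their median was 0.1 (SE 0.09, 5 genes), which does not decide. Weaker glucocorticoid signalling could lower other glucocorticoid-raised genes, but their median was 0.078 (SE 0.107), with 7 of 10 genes higher and 3 lower. This met the bound written against the explanation. The verdict was later made open because the genes go both ways, so the test decides nothing. Other probes of the 4 genes had a median of -0.535 (SE 0.205), with 3 of 4 lower and 1 higher. That median met the bound first written against array noise. A spread was later added to the test and the verdict became open, as these probes are too few to exclude array noise. The 4 genes were picked for agreeing on both arrays, so that agreement is no test of noise or of a dye effect.

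For higher photoreceptor genes, more photoreceptor cells would raise all abundant transcripts, and the brighter 14 members had a median of 0.225 (SE 0.102). At least 0.5 was needed for this explanation and a value under 0.3 by more than the error against it, so it may or may not hold. A first version of the test left out passing genes, giving 0.19 (SE 0.10) over 13 members, which met the bound against this explanation; it was replaced, and the verdict became open, because such a list excludes nothing. With the dyes swapped as labelled, the median on the array nearer 0 was 0.173 (SE 0.078), on the same side as the other. Being apart had already required the same side. It had not required a median outside the random range on each array, here at percentiles 99.9 and 100. This argues against a dye effect as the whole cause, but not against a part in it. A first version used the dye component, -0.05 (SE 0.05), and left this open. Without passing genes the dye component was -0.11 at percentile 2.29, outside the random range. Second probes of 21 members had a median of 0.224 (SE 0.066), above the range of random second probes, which argues against noise of single probes.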
